A study of Mus musculus with 2 samples.

How the data were processed

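Single-cell RNA sequencing on the 10x platform was read from 2 libraries of mouse cells, 1 from mice given a colotomy and 1 from mice given a sham operation, each taken on postoperative day 14 from C57BL/6 animals aged 8 to 12 weeks. Each library pools cells of bowel and of mesenteric adipose tissue (MAT, the fat along the bowel), which had been marked with hashtag antibodies before pooling. The deposited matrices hold raw UMI counts (unit: count) for 32285 genes and 2 hashtags per barcode, per the file headers made with Cell Ranger 6.0.0. Per the submitters' processing notes the reads were aligned to mm10, STAR 2.5.1b was used, and Seurat and Space Ranger are also listed with no role given. The settings of the cell calling are not stated. A reference table of the submitters pairs hashtag 1 with bowel and hashtag 2 with MAT for both libraries, and tissue names rest on it alone.

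Barcodes with at least 500 gene UMIs, at least 300 genes and under 20% mitochondrial UMIs were kept. Hashtags were called per library with a Gaussian mixture of 2 components on log hashtag UMIs (scikit-learn 1.9.0, posterior over 0.5), and barcodes positive for both hashtags were removed. Scrublet, run per library through scanpy 1.11.5, called 0 barcodes in either library, so that no other barcodes were removed as doublets. The mixture components lay at most 0.975 lower-component SDs apart, so barcodes positive for both hashtags need not be doublets. Kept cells of both libraries were clustered together without integration: counts per 10000 on the log scale, 2000 variable genes with the library as batch, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 (igraph 0.11.9). This gave 26 clusters.

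A cluster took a class name from 22 lists of cell type markers. A marker counted when it was found in at least 10% of the cluster's cells and at 2 or more times the CPM (UMI counts of a gene scaled by the UMIs of all genes) of all other cells, and a name needed at least 3 markers, no set of at least 3 markers with 0.5 or more of its share of another lineage and no stronger set of another class among the 10 leading genes. By this rule 15 clusters were named and 11 were left unnamed. The marker lists were fixed before the data were examined, as were the gene lists, the rule for named genes, the filters and most alternatives. The naming rule itself, 2 further gene lists for bowel and adipose fibroblasts, and the alternatives on Scrublet scores, sex-linked genes, single clusters, unnamed lymphocyte clusters and the named non-immune denominator were chosen after seeing the data.

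With 1 library per group there is no replicate, so no test of the operation was made and no p-value is given. UMIs were summed over a class in each library and given as CPM of the class total. Shares of cells have exact Clopper-Pearson intervals, CPM values exact Poisson intervals and ratios exact conditional binomial intervals, each at 95% (scipy 1.17.1), and these cover counting error only, not differences between animals, digestions or libraries. A count of 0 is set to a floor of 3 counts for a ratio, which is then a bound. After subtraction of free RNA a value at or below 0 takes the same floor, which is higher in CPM in a class with fewer UMIs. In fibroblast-like cells the 12 genes with the largest and the 12 with the smallest ratio are named, and in macrophage-like, vascular endothelial-like and mesothelial-like cells the 6 and the 6. These needed at least 50 UMIs and 100 CPM in the library where they were higher, a CPM there not below that of all other kept cells, and were not mitochondrial, ribosomal, haemoglobin, immunoglobulin or unnamed gene models. Of the genes this rule names, 1 is not reported here. A set of 17 genes of fibroblast activation and progenitors is given whatever its ratio. Classes were compared where both libraries held at least 100 cells of the class, except that genes of neutrophil-like cells (160 and 58) are given among the other observations.

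For each of 24 fixed gene lists, the members with at least 10 UMIs over both libraries were counted as at least 1.5-fold higher or lower in the colotomy library. The median log2 ratio of a list was set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. Shares of fibroblast-like cells with a UMI of a gene were read after thinning each cell to 1000 UMIs, with T cell-like and B cell-like cells as background. The ratios and intervals were tested on simulated data with 200 changed genes among 10438. Of the unchanged genes, 1.62% passed 1.5-fold and 95.6% had an interval that held the true ratio, and the same figures for genes doubled were 100% and 98%. The simulated sums were Poisson counts from a shared profile, which is what the intervals assume. These figures therefore check the calculation under counting error only, not differences between cells or libraries.

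Depth differed between the libraries. The colotomy library held 15547 barcodes and 12002711 gene UMIs, with a median of 619 per barcode, and 9246 barcodes passed the filter. The sham library held 44814 barcodes and 74006762 gene UMIs, with a median of 1315, and 42143 passed. Removing double-hashtag barcodes left 8477 and 40145 cells. Coordinates come from GENCODE vM21 on mm10, matched by Ensembl identifier. Alternatives covered the cell filter, doublets, clustering resolution, denominators, scaling, weighting, hashtag mix, hashtag rule, free RNA, thresholds and thinning depth. No deposited per-sample column was left unused (0).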

Results

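The data are single-cell gene counts of mouse bowel and mesenteric fat, 14 days after a colotomy (an incision of the colon) or a sham operation. Each group has 1 library, which pools both tissues, so every difference given here is a difference between 2 libraries and has no replicate. The colotomy library held 12002711 gene UMIs over 15547 barcodes and gave 8477 kept cells, and the sham library held 74006762 over 44814 and gave 40145. Median depth per barcode was 619 and 1315 UMIs, mitochondrial genes took 10.3% and 7.62% of UMIs, and hashtag antibodies gave 5.16 and 1.31 UMIs per gene UMI.

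The first comparison asks which cell types made up the tissues after the wound. Fibroblast-like cells, which build connective tissue, were 41.4% of kept cells in the colotomy library (95% interval 40.3% to 42.5%) and 12.8% in the sham library (12.5% to 13.1%). Epithelial-like cells were 15.7% and 5.57%, with goblet cells apart in an unnamed cluster, macrophage-like cells 593 of 8477 cells and 4.52%, and antibody-secreting plasma cell-like cells 6.79% and 2.48%. Neutrophil-like cells were 1.89% (160 cells) and 0.144% (58 cells). T cell-like cells were lower after colotomy, at 1.76% against 9.71%, as were B cell-like cells at 0.885% against 11.4% and erythroid-like cells at 0.602% against 4.77%. Mesothelial-like cells, the lining of the peritoneum, were 1.90% and 1.72%, vascular endothelial-like cells 1.73% and 2.51%, and smooth muscle-like cells 0.661% and 0.770%. Unnamed clusters held 19.7% and 43.6% of cells, and the largest part in the sham library lay in 6 clusters nearest the B cell or T cell markers. An unnamed cluster led by the goblet cell genes Spink4, Muc2 and Agr2 held 10.7% and 1.72%. Among named non-immune cells, fibroblast-like cells were 67.5% and 54.8%, epithelial-like cells 25.5% and 23.8%, mesothelial-like cells 3.10% and 7.35%, vascular endothelial-like cells 2.83% and 10.7% and smooth muscle-like cells 1.08% and 3.29%, so that much of the gap in the fibroblast-like share went with the number of immune and unnamed cells. Of the 10 other named classes, 5 were higher in the colotomy library, mesothelial-like cells among them with overlapping intervals (1.62% to 2.21% and 1.59% to 1.85%), and 3 were with at least 1000 UMIs and 500 genes per cell. Under that setting no cluster was named neutrophil, so neutrophil-like cells were left out of the count.

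**Figure D1:**
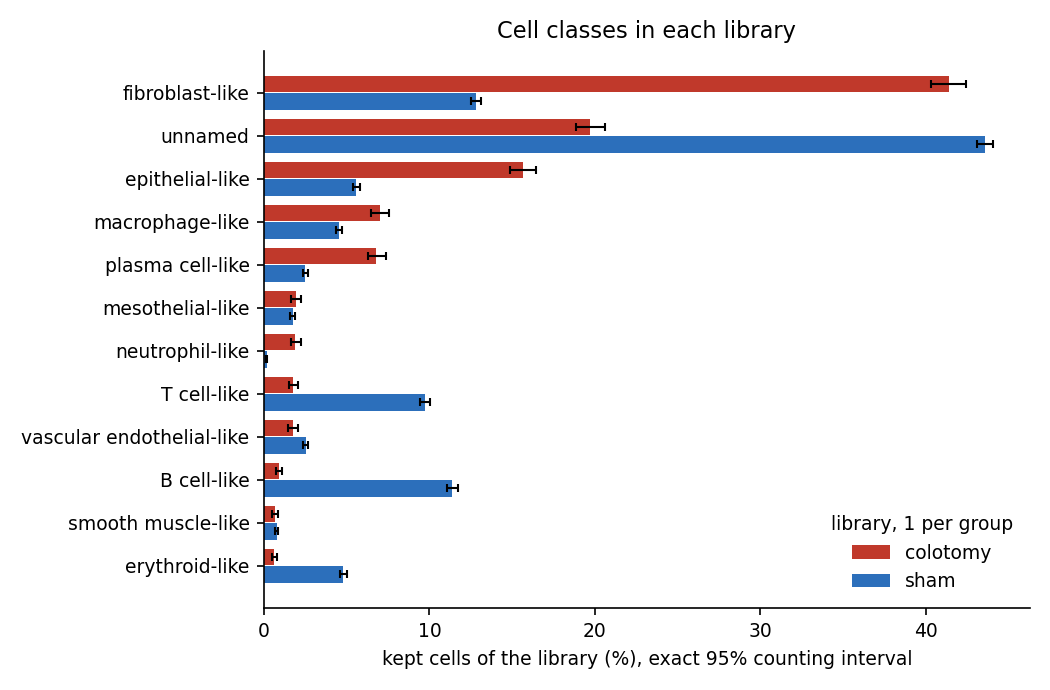
Share of kept cells (%) of each cell class in the colotomy library (8477 cells) and the sham library (40145 cells), with exact 95% counting intervals. Fibroblast-like cells reached 41.4% against 12.8%, and unnamed clusters 19.7% against 43.6%.

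The next comparison asks how fibroblasts differed after the wound. Fibroblast-like cells of the colotomy library held more RNA of fibrillar collagen and of genes of activated fibroblasts, and less of others such as Inmt and Abca8a. Col1a1, the main chain of type I collagen, stood at 10388 CPM against 1836.5 CPM, 5.66-fold higher (5.55 to 5.77). Col3a1, of type III collagen, stood at 8503 against 3699 CPM, 2.30-fold higher (2.26 to 2.34). Cthrc1, a secreted protein of scar-forming fibroblasts, stood at 81.7 against 9.14 CPM, 8.94-fold higher (6.93 to 11.6). Saa3, an acute-phase protein, was 18.8-fold higher (16.2 to 21.9). These sums rest on 3509 cells with 2900172 UMIs and 5144 cells with 8970500 UMIs.

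Xist, the RNA that silences an X chromosome in female cells, had the largest ratio of the 12 genes that were highest relative to sham, at 500.3 against 1.56 CPM (log2 8.32). Matrix genes among the 12 were Timp1, an inhibitor of matrix proteases, at 364 against 52.1 CPM (2.80), the collagen Col12a1 (2.76), fibromodulin Fmod (3.41), fibrillin Fbn2 (2.66) and Thbs2, a thrombospondin (2.62). The growth factors Ptn (3.29) and Mdk (2.75) and the WNT ligand Wnt4 (3.08) were also among them, with the protease inhibitor-like gene Ctla2a (3.45) and the immediate early gene Ier3 (3.13). The 12 genes lowest relative to sham were led by the methyltransferase Inmt, at 19.0 against 125.6 CPM (-2.73), the transporter Abca8a (-1.79), and Adamdec1, a protease of gut stroma (-1.36). Vit (-1.34), Smpd3 (-1.21), Klf9 (-1.14), Ablim1 (-1.11), Errfi1 (-1.07), Hmcn2 (-1.01), AY036118, which overlaps ribosomal repeats (158 against 316 CPM), gelsolin Gsn (-0.99) and the chemokine Ccl11 (-0.98) made up the rest.

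Among genes chosen in advance, the matricellular genes Postn (1201 against 455 CPM, 1.40) and Tnc (147 against 42.1 CPM, 1.80) and the contractile actin gene Acta2 (118 against 44.6 CPM, 1.40) were higher in the colotomy library. So were Fn1, for fibronectin (0.59), and the mechanical-response genes Ccn2 (1.34), Ccn1 (0.88), Piezo1 (0.88), Yap1 (0.72) and Wwtr1 (0.60). Pi16 and Dpp4, markers of progenitor-like fibroblasts, differed less, at 647 against 524 CPM (0.30) and 86.5 against 63.3 CPM (0.45). With at least 1000 UMIs and 500 genes per cell, Pi16 turned to -0.07. Fap was not detectably different (17.9 against 18.6 CPM, interval -0.53 to 0.40). Ankrd1 had 3 against 1 UMIs, a log2 ratio of 3.21 with an interval of -0.42 to 8.93. In mm10, Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042, Cthrc1 (ENSMUSG00000054196) on chromosome 15 from 39076932 to 39087121, and Timp1 (ENSMUSG00000001131) on chromosome X from 20870166 to 20874735.

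**Figure D2:**
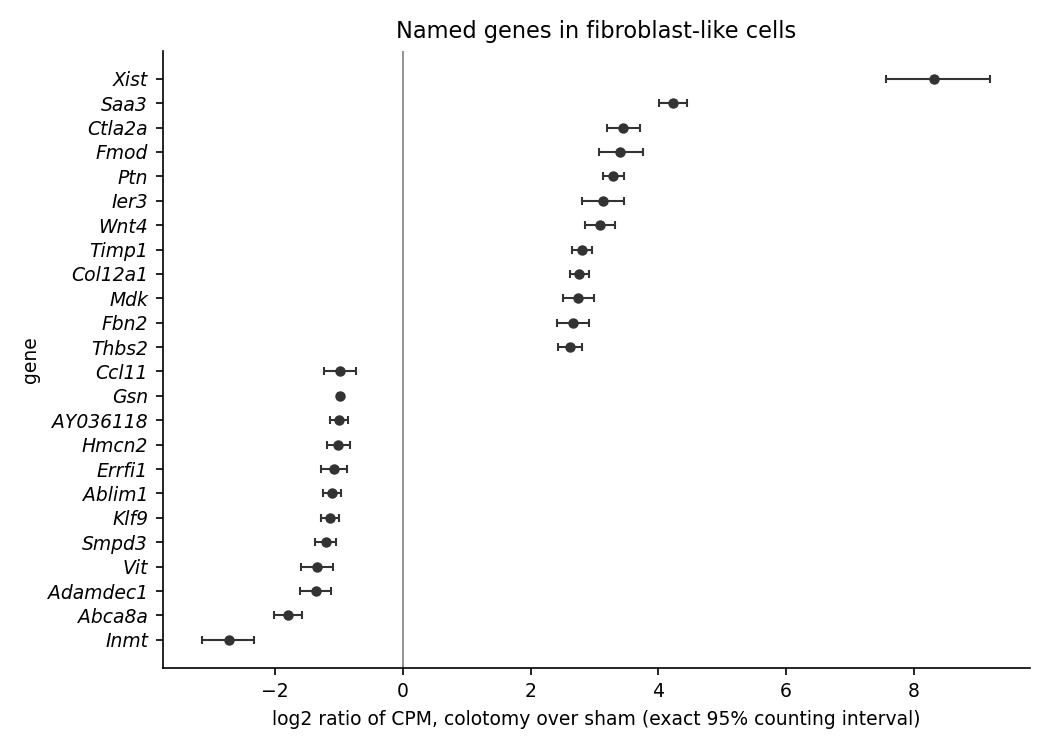
Log2 ratio of CPM, colotomy over sham, of the 12 highest and the 12 lowest named genes in fibroblast-like cells, with exact 95% counting intervals. Xist stands apart at 8.32, followed by Saa3 at 4.23, and Inmt is lowest at -2.73.

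Gene lists fixed in advance showed the same picture by function. Of 16 genes of fibrillar collagen and its crosslinking, 15 were at least 1.5-fold higher in colotomy fibroblast-like cells and 0 lower, with a median log2 ratio of 1.27; Col11a1 (59.3 against 1.23 CPM), the prolyl hydroxylase P4ha3 (3.04) and the lysyl hydroxylase Plod2 (1.87) were examples besides Col1a1. Of 20 genes of activated or mechanosensitive fibroblasts, 19 were higher and 0 lower (median 1.87), led by Spp1, for osteopontin (6.53), Cthrc1 and Timp1. Spp1 at 185.5 CPM in these cells lay below its 436.4 CPM in all other cells of the library. Of 17 matrix proteases and inhibitors, 13 were higher and 0 lower (median 1.28), among them Mmp14 (2.03) and Mmp9 (2.04). Of 20 cytokines and chemokines, 11 were higher and 1 lower (median 0.70), with Saa3, the neutrophil attractant Cxcl2 (4.23) and Cxcl5 (2.90) in the lead. These 4 medians lay above all 10000 random lists, but in cells with Y-linked RNA and without Xist the cytokine list lay within their central 95% (0.02).

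Targets of the mechanical regulators YAP and TAZ were more mixed: of 21 measured, 10 were higher and 1 lower (median 0.57), with Igfbp3 (1.35) and Ccn2 as examples. Genes of lipid handling were 9 higher and 2 lower of 18 (0.53), with the adipokine Cfd (3.91) and Cebpb (2.14) higher and Apod (-1.74) lower. Complement genes were 5 higher and 1 lower of 10 (0.58), with C1s1 (1.60) and C4b (1.06) higher and C7 (-1.65) lower. TGF-beta response genes were 6 higher and 2 lower of 16 (0.35), with Ltbp2 (2.85) and Pmepa1 (1.37) higher and Tgfb1 itself lower (-1.16). These 4 medians also lay above the central 95% of random lists. YAP and TAZ targets lost this place within cluster 3 of the fibroblast-like cells (0.07), lipid genes within cluster 4 (0.30) and in cells with Y-linked RNA (0.08), and complement genes with at least 1000 UMIs and 500 genes per cell (0.29), within cluster 3 (0.37) and within cluster 4 (0.29). TGF-beta response genes lost it at Leiden resolution 2 (0.29), without the highest Scrublet scores (0.25), in cells with Y-linked RNA (0.22), within cluster 3 (0.08) and within cluster 4 (-0.04). The interferon response was lower, with 0 of 16 genes higher and 7 lower (median -0.49), among them the immunoproteasome gene Psmb8 (-1.21) and Irf7 (-1.06). Proliferation genes were 1 higher and 5 lower of 14 (-0.42), with Ccnb2 (-1.15) and Mcm5 (-0.86), and both medians lay below the central 95% of random lists. The proliferation median turned to 0.15 without the highest Scrublet scores and to 0.095 as a mean over cells. It lay within the range at Leiden resolution 0.5 and with at least 1000 UMIs and 500 genes (-0.11). Both lists lay within the range in cluster 3 and in cluster 4.

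Within that range were basement membrane and other collagens (6 higher and 0 lower of 16, median 0.22), the actin cytoskeleton (5 and 0 of 20, 0.22), WNT and BMP ligands and inhibitors (6 and 4 of 15, 0.24, with Sfrp2 at 2.14 and Bmp5 at -2.79) and Pi16 or universal fibroblast genes (1 and 1 of 15, 0.05). The actin list lay above it with at least 1000 UMIs and 500 genes (0.35), the WNT and BMP list in cells with Y-linked RNA (0.51) and the Pi16 list within cluster 3 (0.86). Of the lists added after seeing the clusters, bowel fibroblast genes were 3 higher and 5 lower of 13 (median -0.37) and adipose fibroblast genes 4 higher and 2 lower of 12 (0.15), both within the range. Immediate early genes that tissue digestion can induce were 6 higher and 0 lower of 16 (0.41). RNA typical of other cells was 7 higher and 3 lower of 16 (0.54), with the neutrophil gene S100a8 (5.10) and the epithelial defence gene Reg3b (5.36) higher and haemoglobin Hbb-bs lower (-1.95). Both of these medians lay above the central 95% of random lists, the former not at Leiden resolution 2 (0.31), the latter not within cluster 4 (0.04), and neither in cells with Y-linked RNA (0.39 and 0.34).

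**Figure D3:**
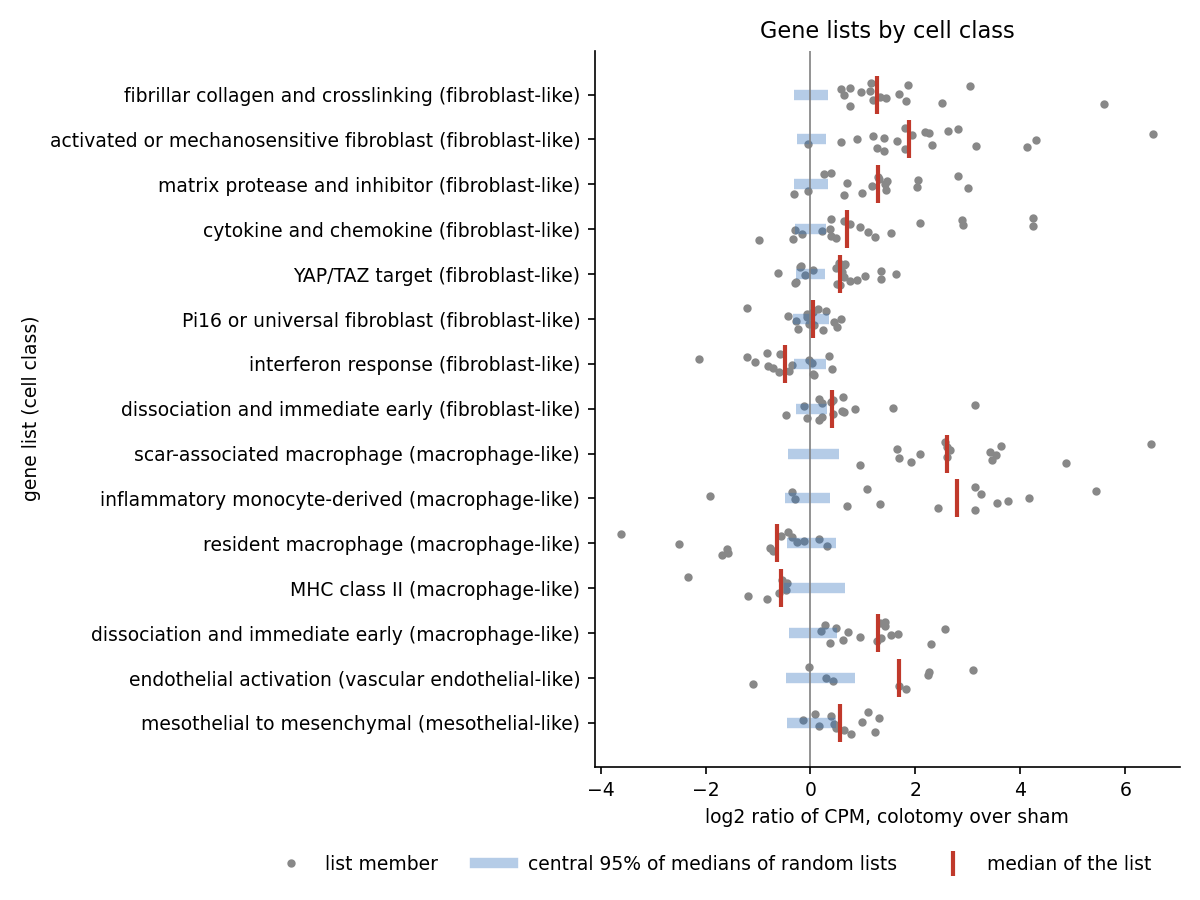
Log2 ratio of CPM, colotomy over sham, of the members of 15 gene lists by cell class (grey points), with each list's median (red) and the central 95% of medians of matched random lists (blue). The scar-associated list of macrophage-like cells has a median of 2.61 and the fibrillar collagen list of fibroblast-like cells 1.27.

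The medians of the collagen and activation lists were smaller within single clusters, while some other differences were larger. Fibroblast-like cells fell into cluster 3, which held 15.9% of colotomy and 12.3% of sham cells, and cluster 4, which held 25.5% and 0.538%. Col1a1 was 3469 against 1427 CPM within cluster 3 and 14205 against 9715 CPM within cluster 4. Col1a1, Col1a2 and Col3a1 also belong to the markers that name the class, and Ptn, Col1a1, Timp1, Col12a1, Thbs2 and Col1a2 are among the leading genes of cluster 4, so the split itself narrows their ratios. Within cluster 3 the collagen list had a median of 0.75 and the activation list 0.67, and within cluster 4 these were 0.27 and 0.47. Tnc turned to -0.54 within cluster 3 and to -0.10 within cluster 4, Acta2 to -0.44 and Ccn1 to -0.58 within cluster 3, and Col3a1 to -0.32 and Postn to -0.25 within cluster 4. Pi16 genes were 11 higher and 0 lower of 15 within cluster 3, with a median of 0.86. At Leiden resolution 2 a fibroblast-like cluster led by Pi16 held 749 colotomy and 1999 sham cells. Another led by Inmt held 269 and 1851, and another led by Adamdec1 160 and 879. For Pi16 genes and for the lowest genes Inmt, Abca8a, Adamdec1 and Hmcn2, a different mix of finer clusters thus cannot be told apart from a change within cells.

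Sex-linked RNA differed as well. Summed over all kept cells, Xist stood at 394 CPM in the colotomy library (380.2 to 408) and 0.751 CPM in the sham library (0.558 to 0.991), while 4 Y-linked genes (Ddx3y, Uty, Eif2s3y and Kdm5d) together stood at 155 and 210.3 CPM. Xist differed between classes, from 107 CPM in plasma cell-like to 1696 CPM in mesothelial-like cells of the colotomy library. In fibroblast-like cells with a Y-linked UMI and no Xist UMI, of which there were 382 and 1521, Col1a1 was 11609 against 1820 CPM, the collagen list had a median of 1.43 and the activation list 1.79. In the same cells the cytokine list had a median of 0.02 and the lipid list 0.08, so that both lists moved to about 0, though Saa3 was still 300.7 against 13.6 CPM and Cxcl2 152 against 9.16 CPM. These sums rest on 342500 colotomy and 3167501 sham UMIs. Neither list median has a counting interval in these cells, so counting error is not excluded for the move.

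**Figure D4:**
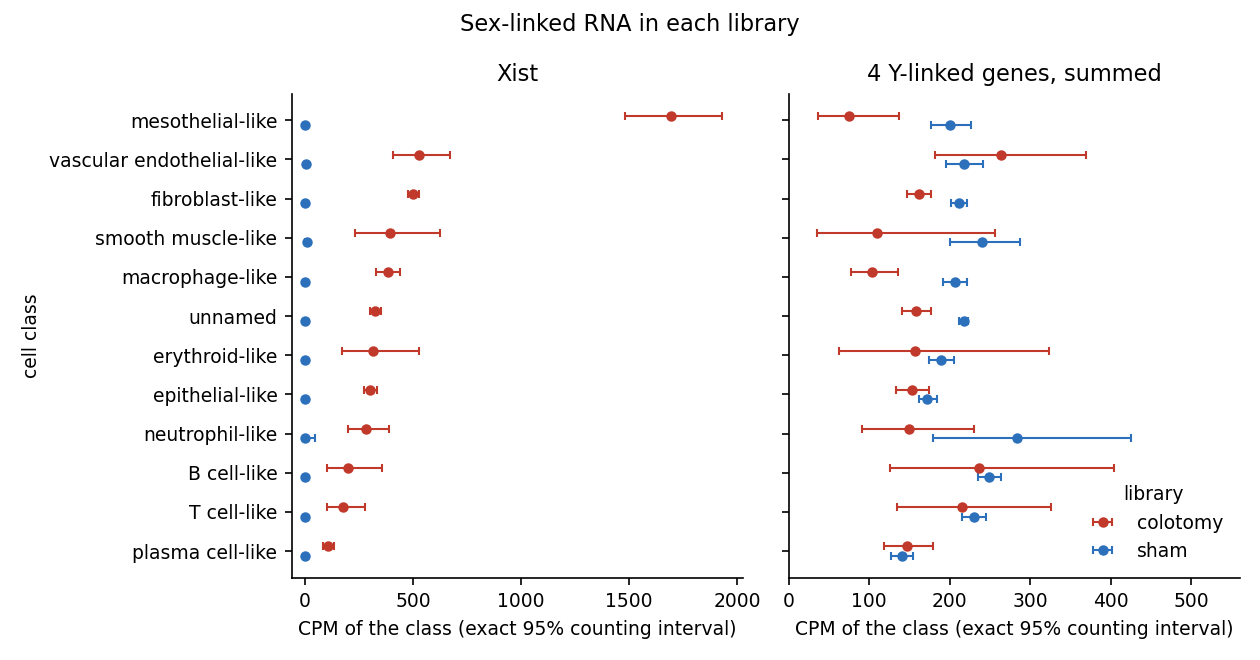
CPM of Xist (left) and of 4 Y-linked genes summed (right) by cell class and library, with exact 95% counting intervals. In the colotomy library Xist reached 1696 CPM in mesothelial-like cells and 107 CPM in plasma cell-like cells, and in the sham library it stayed at or below 7.82 CPM in each class.

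How common activated cells were among fibroblasts was asked by counting cells with a UMI at a thinned depth of 1000. Cthrc1 was found in 6.77% of colotomy cells (5.05% to 8.85%) and 0.831% of sham cells (0.579% to 1.15%). Timp1 was found in 27.6% and 4.30%, Postn in 54.0% and 28.6%, Acta2 in 8.56% and 2.28%, and Tnc in 11.9% and 2.90%. Pi16 (30.4% and 28.4%), Dpp4 (8.01% and 6.01%) and Fap (1.80% and 2.07%) had overlapping intervals. Thinned to 500 UMIs, which leaves out 0 cells, Pi16 was 23.7% (22.3% to 25.2%) and 17.5% (16.5% to 18.6%), and Dpp4 4.22% (3.58% to 4.94%) and 2.80% (2.37% to 3.29%). T cell-like and B cell-like cells of the sham library (3608 cells, median depth 1288 against 1710.5 in its fibroblast-like cells) gave 0.887% for Postn, 0.859% for Acta2, 0.804% for Pi16, 0.166% for Tnc, 0.139% for Timp1 and 0.111% for Fap, with Cthrc1 in 0 cells, which allows up to 0.102%. They gave 4.82% for Dpp4, which T cells also make. Those of the colotomy library were 23 cells (median depth 1174 against 1243.5), with a UMI of Postn and of Tnc in 4.35% each and 0 for the others, which allows up to 14.8%. Thinning left 724 of 3509 colotomy cells and 4212 of 5144 sham cells, and without it Pi16 (30.55% and 34.6%) and Dpp4 (6.498% and 9.66%) were lower in the colotomy library.

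The third comparison reads the other cell types. Macrophage-like cells of the colotomy library (593 cells, 509461 UMIs) held far more RNA of scar-associated and inflammatory genes than those of the sham library (1814 cells, 3542330 UMIs), and less of tissue-resident genes. The class is cluster 9, whose leading genes include Folr2, Cbr2 and Cd163. Cluster 8, nearest the macrophage markers with Lyz1 and Ccr2 among its leading genes (480 and 1956 cells), stayed unnamed and is not part of it. Spp1 stood at 3464 against 38.4 CPM, a log2 ratio of 6.50 (6.24 to 6.76). The prostaglandin synthase Ptgs2 (5.45), thrombospondin Thbs1 (5.17), arginase Arg1 (4.87), the protease Ctsk (4.86) and the interleukin-1 antagonist Il1rn (4.68) followed. Lowest were Il4i1 (-2.92), Ednrb (-2.54), Lyve1, a receptor of resident macrophages (-2.50), the chemokine Ccl24 (-2.37), the leukotriene synthase Ltc4s (-2.19) and Klhl6 (-2.18). Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050 of mm10.

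All 15 genes of the scar-associated macrophage list were at least 1.5-fold higher (median 2.61), with Mmp12 (3.64) and the lipid chaperone Fabp5 (3.53) as further examples. Of 14 measured inflammatory genes, 11 were higher and 1 lower (2.78), among them Il1b (4.16), Cxcl3 (3.76) and Cxcl2 (3.56). Digestion-related immediate early genes moved with both lists, with 12 higher and 0 lower of 16 (1.29), led by Ier3 (2.56) and Atf3 (2.29). The resident list was 0 higher and 7 lower of 14 (-0.64), with Timd4 at 2 against 169 UMIs (-3.60, interval -6.66 to -1.73) and Folr2 (-1.59). Genes of MHC class II were 0 higher and 4 lower of 8 (-0.57), with H2-Oa (-2.34), Ciita (-1.20) and Cd74 (-0.83). Proliferation genes were 0 higher and 9 lower of 14 (-1.16), with Top2a (-1.51) and Mki67 (-1.41). These medians lay outside the central 95% of random lists, and the list of RNA from other cells, 7 higher and 2 lower of 16 (0.38), lay within it, with S100a8 at 4.98. At Leiden resolution 0.5 the proliferation median turned to 0.28 and the resident median was -0.21, within the range of random lists. With the hashtags weighted equally the proliferation median was 0.04, the inflammatory median was 1.56 and MHC class II (-0.62) came within the range. The proliferation median was also within it with at least 1000 UMIs and 500 genes (-0.32), where the list of RNA from other cells lay above it (0.88), as it did at resolution 0.5, at resolution 2 and after free-RNA subtraction. The value after subtraction is the ratio of the floors and shows no rise.

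Vascular endothelial-like cells (147 and 1008 cells; 125438 and 1608275 UMIs) were higher after colotomy in genes of activation. The leading genes of their cluster include the lymphatic genes Ccl21a and Mmrn1, so the class also holds lymphatic cells, whose share was not measured. Lrg1, a venular protein of inflammation, had a log2 ratio of 2.24 (1.82 to 2.64), after Xist at 6.92. Prox1, the regulator of lymphatic identity (2.17), Sox4 (2.05), Smad1 (1.94) and S100a16 (1.89) followed. Timp4 (2 against 177 UMIs, -2.79, interval -5.84 to -0.91), Rbp7 (-2.34), Adgre5 (3 against 187 UMIs, -2.28, interval -4.57 to -0.71), Atp8a1 (3 against 162 UMIs, -2.07, interval -4.37 to -0.50), Rb1cc1 (-1.89) and Brwd1 (-1.87) were lowest. Of 9 activation genes 5 were higher and 1 lower (median 1.68, above the central 95% of random lists), with the adhesion molecule Madcam1 (2.25) and the venular Ackr1 (1.82) higher and Cxcl12 lower (-1.10). With the hashtags weighted equally this median was 0.65, within the range, and Adgre5 turned to 0.05. Within the range of random lists were angiogenic genes (6 and 0 of 14, 0.50, with Col4a1 at 1.06, but a median of -0.21 with at least 1000 UMIs and 500 genes), immediate early genes (5 and 1 of 16, 0.14), proliferation (4 and 5 of 14, -0.14) and RNA of other cells (5 and 4 of 14, 0.12, with S100a8 at 6.44 and Hbb-bs at -3.82, the latter 3 against 545 UMIs, interval -6.11 to -2.27). The last list lay below the range with at least 1000 UMIs and 500 genes (-0.48) and above it after free-RNA subtraction (2.99). After that subtraction the floor is higher in CPM in the smaller colotomy class and can lift a ratio, so 2.99 is not shown to be a rise. Scaling by the median of ratios in place of totals shifted every endothelial ratio by -0.18 and every mesothelial ratio by -0.14.

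Mesothelial-like cells (161 and 690 cells; 133864 and 1328351 UMIs) differed little in the list of identity genes and were higher in the list of mesenchymal genes, though not under every setting. A Xist UMI was found in 57.1% of these cells after colotomy and 0.145% after sham, and a Y-linked UMI in 6.21% and 32.0%. Sex or animal thus cannot be told apart from the operation in this class, where cells with Y-linked RNA were not read separately. Xist led (10.14, on 2 UMIs in the sham library, interval 8.27 to 13.19), followed by the growth factor Igf1 at 799 against 61.7 CPM (3.69), Cebpb (2.22), the complement gene C1s1 (1.80) and Maf (1.61). Fmo2 (-2.36), the B cell attractant Cxcl13 (-2.02), AY036118 (-1.87), Phf3 (-1.58), Fmod (-1.33) and Rb1cc1 (-1.26) were lowest, and Rb1cc1 turned to 0.29 with the hashtags weighted equally. Identity genes were 1 higher and 1 lower of 14 (median 0.11), with Krt8 (0.99) and Muc16 (-0.75). Mesenchymal genes were 6 higher and 0 lower of 12 (0.56, above the central 95%), with Col1a1 (1.23) and Zeb2 (1.09), but within the range with at least 1000 UMIs and 500 genes (0.31), with the hashtags weighted equally (0.56) and after the free-RNA profile was subtracted (0.09). Immediate early genes were 6 higher and 1 lower of 16 (0.49) and RNA of other cells 7 and 5 of 15 (0.50, with Car1 at 2.43 and Hbb-bs at -3.38), both above that range but within it with at least 1000 UMIs and 500 genes (0.20 and 0.35). With the hashtags weighted equally the former was within it (0.33) and the latter turned to -0.90, and under 10% mitochondrial UMIs the former was within it (0.49), as at Leiden resolution 0.5 (0.43), and the latter turned to -0.24. Proliferation was 1 higher and 6 lower of 13 (-0.58), below it, with Mki67 at 1 against 73 UMIs (-2.88, interval -8.20 to -0.36), and turned to 1.30 with at least 1000 UMIs and 500 genes, to 0.10 under 10% mitochondrial UMIs and to 0.90 after free-RNA subtraction. It also lay within the range without the highest Scrublet scores (-0.54), as a mean over cells (-0.27) and with the hashtags weighted equally (-0.99). With at least 1000 UMIs and 500 genes the class held 36 colotomy and 577 sham cells. Colotomy counts of 0, and values at or below 0 after subtraction, take the floor, which can lift a ratio. The positive proliferation medians are thus not shown to be a rise.

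The last comparison sets bowel against MAT within each library. Fibroblast-like cells made up like shares of bowel-called and MAT-called cells, 39.2% (36.1% to 42.4%) and 40.7% (38.1% to 43.3%) after colotomy and 13.7% (12.3% to 15.2%) and 13.2% (12.2% to 14.2%) after sham. In the colotomy library mesothelial-like cells were 1.16% of bowel-called and 4.82% of MAT-called cells, and epithelial-like cells 17.2% and 10.9%. In the sham library mesothelial-like cells were 49 of 2254 and 66 of 4390, and epithelial-like cells 5.06% and 7.63%. Col1a1 in fibroblast-like cells was 10571 CPM in bowel-called and 8846 CPM in MAT-called cells after colotomy, and 1609 and 1963 CPM after sham. The hashtags did not separate the tissues: the components of the mixtures lay at most 0.975 lower-component SDs apart, and 6141 of 9246 and 33501 of 42143 barcodes were positive for neither. The median log2 ratio of bowel to MAT hashtag UMIs was 2.64 in the colotomy and -1.33 in the sham library, and under a rule of 3 times the other hashtag only 16 colotomy cells were called MAT.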

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

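The alternatives that leave out the 10% of cells with the highest Scrublet scores, take cells with Y-linked RNA, take cluster 3 or 4 alone, take named non-immune cells as the denominator or count unnamed lymphocyte clusters were chosen after the result was seen. Over all alternatives, 601 values of single genes stayed within their counting interval, 189 moved beyond it in the same direction or without a call, and 13 reversed. For list medians these counts were 231, 104 and 10, and for shares outside the main results 55, 53 and 1. The fibroblast-like share stayed higher in the colotomy library under each alternative run. It was 30.8% against 15.1% with at least 1000 UMIs and 500 genes, 46.8% against 14.2% under 10% mitochondrial UMIs and 37.3% against 12.3% at resolution 2. Without the highest Scrublet scores it was 40.2% against 10.9%, and with hashtags weighted equally 39.9% against 13.5%. Without the named immune classes it was 50.7% against 17.9%, but the unnamed lymphocyte clusters stayed in that denominator. Of named non-immune cells it was 67.5% against 54.8%. For these and the values that follow, the cause was not tested. With at least 1000 UMIs, 3 other classes in place of 5 were higher in the colotomy library. No cluster was named neutrophil under that setting, so neutrophil-like cells were not counted there.

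Of 16 lists in fibroblast-like cells, 10 lay above and 2 below the central 95% of random lists, with 120 members higher and 27 lower. The number above was 6 in cells with Y-linked RNA and 6 in cluster 4. The number below was 1 with at least 1000 UMIs, 1 at resolution 0.5, 1 without the highest Scrublet scores, 1 as a mean over cells, 0 in cluster 3 and 0 in cluster 4. Members higher numbered 70 in cluster 4 and 79 at a 2-fold threshold, and members lower 42 in cells with Y-linked RNA and 13 at that threshold. Of the 12 lowest genes, 6 stayed 1.5-fold lower in cluster 3 and 5 in cluster 4. In the other classes 7 lists lay above and 4 below. With hashtags weighted equally these were 3 and 2, and at resolution 0.5 the number below was 2. The hashtag rule of 3 times the other gave fibroblast-like shares of 43.8% of 16 cells for MAT after colotomy, and 11.7% for bowel and 11.6% for MAT after sham.

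These log2 values reversed. With at least 1000 UMIs, Pi16 was -0.0698, Rb1cc1 of mesothelial-like cells 0.00235 and their proliferation list 1.30. In cluster 3, Ccn1 was -0.58, Tnc -0.54 and Acta2 -0.44. In cluster 4, Vit was 0.60, Errfi1 0.76, Ccl11 0.12, Col3a1 -0.32, Postn -0.25, Tnc -0.10 and the TGF-beta list -0.0389. The fibroblast proliferation list was 0.15 without the highest Scrublet scores and 0.095 as a mean over cells. The macrophage proliferation list was 0.28 at resolution 0.5 and 0.0425 with hashtags weighted equally, where Adgre5 was 0.0476, Rb1cc1 0.29 and the mesothelial list of other cells' RNA -0.90. Under 10% mitochondrial UMIs that list was -0.24 and the mesothelial proliferation list 0.10, which was 0.90 after subtraction of free RNA. After that subtraction the lists of other cells' RNA stood at 1.63 in fibroblast-like and 2.80 in macrophage-like cells. Both values are the ratio of the floors, which follows from the class totals where a gene fell to the floor in both libraries. They therefore show no rise. The floor can also lift the mesothelial proliferation medians of 1.30 and 0.90. The share with a Dpp4 UMI was -0.57 without thinning. At 2000 UMIs Dpp4 had 0 of 46 colotomy cells and gave no ratio, and the T cell-like and B cell-like background of that library held 0 cells. The endothelial-like and mesothelial-like classes rest on 147 and 161 colotomy cells, which limits what their gene values can show.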

Other observations

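Except for the thinning of sham cells, whose prediction was written before it was run, every test of an explanation here was chosen after the result was seen, as were the genes of the next paragraph. The criterion of the test for lymphoid tissue in the sham sample was also changed after its result was seen. At first a single gene list at or below the colotomy level counted against that explanation, and the stroma genes would have ruled it out. Both lists were then required, because several of the markers are also made by other cells, and this change alone leaves the explanation open. In the test of clusters a fall within each cluster at first counted for a different mix, and after the result was seen it no longer did, because genes of the pattern lead cluster 4. The test of free RNA was likewise moved, after its first result, to the larger subtraction given last.

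Genes of other cell types differed in both directions. Plasma cell-like cells held 32753 against 2800.3 CPM of Ighg1, the IgG1 constant region, 11.7-fold higher (11.4 to 12.0), while Igha, of the gut antibody IgA, was 76679 against 87604 CPM and Ighg2c was 1.07-fold higher (1.04 to 1.12). The cluster led by Ighg1 held 374 of 576 plasma cell-like cells of the colotomy library and 316 of 994 of the sham library, and the cluster led by Igha the rest. Epithelial-like cells held more RNA of the antimicrobial lectins Reg3b (8.14-fold, 7.44 to 8.92) and Reg3g (8.71-fold, 7.38 to 10.3) and of the iron-binding Lcn2 (5.52-fold, 3.68 to 8.35). The water channel Aqp8 of surface enterocytes was 5.47-fold lower (4.19 to 7.27), Saa1 3.08-fold (2.68 to 3.57), Sprr2a3 2.21-fold (1.93 to 2.54) and Duox2 1.93-fold (1.57 to 2.39). The cluster whose leading genes include Saa1, Sprr2a3 and Aqp8 held 297 of 1328 epithelial-like cells of the colotomy library and 1413 of 2237 of the sham library. Neutrophil-like cells (160 and 58, the latter below the minimum for a compared class) held more RNA of granule proteins made during maturation, Ngp (6.17-fold, 5.33 to 7.18), Camp (6.10-fold, 5.02 to 7.48) and Ltf (4.88-fold, 4.03 to 5.97), while Il1b (0.986-fold, 0.785 to 1.24) and Cxcr2 (1.29-fold, 0.764 to 2.25) were not detectably different.

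Fibroblast-like cells of the colotomy library with Xist and without Y-linked UMIs (709 cells) held 8403 CPM of Col1a1, 218 CPM of Timp1 and 134 CPM of Saa3. Those with Y-linked and without Xist UMIs (382 cells) held 11609, 403 and 300.7 CPM, and sham cells of the latter kind (1521) 1820, 49.9 and 13.6 CPM. Adamdec1 was 45.3 CPM (30.1 to 65.4), 2.92 CPM (1 UMI, 0.0739 to 16.3) and 156 CPM (142 to 170.01) in the same order.

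The 36 genes of the collagen and activation lists had a median log2 ratio of 1.67 (1.52 to 1.78) in fibroblast-like cells, 34 of them at least 1.5-fold higher. In cells with Y-linked RNA and without Xist the median was 1.56 (1.47 to 1.78). The pattern was thus not confined to cells with a Xist UMI. In colotomy cells with a Xist UMI and no Y-linked UMI, set against the same sham cells, the median was 1.21 (1.08 to 1.32). The ratio was thus not larger in cells with a Xist UMI. With 1 library per group this does not exclude female cells as a source, because cells without a Xist UMI may include female ones. In the colotomy library 58 fibroblast-like cells held both Xist and Y-linked UMIs, against 96.2 from the product of their shares. Free RNA does not account for the higher median. It was 1.59 after subtraction of an estimated share. The list of RNA from other cells then stood at 1.63 in place of 0.54, but that value is the ratio of the floors and shows no rise. With the whole CPM of all other colotomy cells taken off the colotomy side alone, the median of the 36 genes was still 1.27 (1.22 to 1.33). A different mix of cluster 3 and cluster 4 cannot be told apart from a change within cells, as the median was 0.69 (0.65 to 0.79) within the former and 0.39 (0.26 to 0.50) within the latter, but the clusters were drawn from these genes among others. A different mix of bowel and fat fibroblasts cannot be told apart from the operation, as the medians of 1.63 (1.49 to 1.85) in bowel-called and 1.05 (1.00 to 1.25) in MAT-called cells rest on hashtag components at most 0.975 SDs apart, and the animals and the digestion were not tested.

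Lymphocytes, with unnamed clusters nearest the B cell or T cell markers counted, were 3.79% of colotomy cells (3.39% to 4.22%) and 52.8% of sham cells (52.4% to 53.3%). Loss of shallow lymphocytes below the UMI minimum did not by itself give this gap at the thinning tried. Thinned to 0.362 of their UMIs and filtered again, sham cells still held 32.7% (32.0% to 33.4%). That factor is the lowest ratio of median depths of any named class with at least 100 cells in both libraries. It was taken from cells that had passed the UMI minimum. Unnamed cluster 13 differed more, at a median of 1169 UMIs in colotomy and 3904 in sham cells, so a larger loss is not excluded. Lymphoid follicles or nodes in the sham sample are a possible explanation that stays open, since 8 germinal centre genes were 1.28 times higher there (1.19 to 1.37) but 6 genes of lymphoid stroma 0.822 times (0.744 to 0.910). In the colotomy library the most abundant of these were S1pr2 (39.4 CPM colotomy, 19.7 CPM sham) and Ccl21a (44.5 and 33.7 CPM), and Ccl21a is also made by lymphatic vessels. An unnamed cluster whose leading genes include the germinal centre genes Mef2b, Mybl1, Gcsam and Nuggc held 3.15% of sham and 1.16% of colotomy cells. Its leading genes also include the proliferation genes Top2a and Mki67. An effect of the operation on lymphocytes was not tested.

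Xist and Y-linked UMIs were both present in the colotomy library. Only 113 of its cells held both, against 199 from the product of their shares, a ratio of 0.567 (0.468 to 0.682), which is consistent with cells of male and female mice pooled in this library. Free Xist RNA alone would reach all classes about equally, but Xist was 15.8 times higher in mesothelial-like than in plasma cell-like cells. The labels give neither the sex nor the number of mice, and no biological explanation was tested.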
